A study of Capra hircus with 6 samples.

How the data were processed

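Total RNA was extracted with TRIzol from the ovary of each of 6 goats and made into cDNA libraries with an NEBNext kit, per the labels' protocols. Read length, strand and sequencing date are not given in the sources used here. The authors deposited 1 table per goat with an FPKM value for each of 17504 genes. FPKM divides a gene's fragments by transcript length and by the library's mapped fragments, so values are relative within a library and a few very abundant genes can lower the others. The submitters' processing notes list TopHat2 2.0.10, Bowtie2 2.1.0 and RSEM 1.2.0 without their roles. The genome build and annotation are not given in the sources used here, so no coordinates are printed. The values were not rescaled to a common sum. A second table of the whole series held 6 columns identical to the 6 used and was not used further.

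Genes carry NCBI GeneIDs in the files. Symbols came from a RefSeq gene table of assembly ARS1.2. In it 16459 IDs matched by GeneID and 9 by transcript accession, and 1038 kept their ID, 1036 of them without a match and 2 because both matched TPT1. CYP11A1 (LOC102173131), CYP17A1 (LOC102182663), LDHA (LDH-A) and LYZ (S-LZ) were found through synonyms, and the entry 3BHSD was taken for HSD3B and HSD3B1 by its name after the gene names were seen. Of 632 list entries 85 matched no gene.

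Each library is 1 goat, so the p-values of single genes measure the spread between animals. No label gives a batch. The deposited table of Tibetan 2 is named by another pattern than the other 5, and what this marks is not given in the sources used here; without Tibetan 2, 0 genes passed and 770 had an unadjusted p under 0.05. In the lowest values, ratios of the same gene between libraries pile up at 1 value, as whole fragments would give. The mode of these ratios between 0.15 and 1 FPKM gave relative depths of 1 (Tibetan 1), 1.026 (Tibetan 2), 0.946 (Tibetan 3), 0.962 (Jintang 1), 1.016 (Jintang 2) and 0.927 (Jintang 3). The 10 highest genes held between 7.19% and 9.59% of the FPKM of a library. Genes with at least 1 FPKM in at least 3 of the 6 libraries were kept (13067 genes), and 93 genes were at 0 in all libraries.

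The breeds were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) on log2(FPKM + 1) with breed as the only term, Benjamini-Hochberg adjustment and a threshold of 0.05, 2-sided. Gene lists were tested on the same values with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, and adjusted over the 25 lists with at least 3 tested members. With the preset correlation, camera sets the genes of a list against the other genes. Its p therefore does not measure how the mean of a list varies between animals. Counts adjusted over a list alone use the limma p of its members. Principal components were taken from the centred log2 values. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.

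The lists covered steroidogenesis, cholesterol synthesis and uptake, granulosa, theca, oocyte and luteal cells, LH-surge and ovulation genes, TGF-beta, BMP and activin signalling, litter-size candidate genes, the insulin-like growth factor system, cell cycle, apoptosis and atresia, endothelial, smooth muscle, fibroblast, lymphocyte, macrophage, erythrocyte, surface epithelium, ciliated epithelium and adipocyte markers, hypoxia, immediate-early and heat-shock, interferon-stimulated, ribosomal, mitochondrially encoded and oxidative phosphorylation genes. Lists, tests, alternatives and the rule for naming genes were fixed before the data were examined. The rule names the 12 genes with a symbol and the largest change per direction among those past the threshold (there were none), the members of each list with the smallest p (up to 4), 16 genes of ovarian function, and, where fewer than 10 genes passed in a direction, the 10 with a symbol and the smallest p. It gave 122 genes, of which the text gives part.

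The procedure was tested on simulated data before use, with 13067 genes, the real spread and 50 genes changed at each of 4 fold sizes between 3 and 3 libraries. It recovered 0% of genes with a log2 fold change of 1, 48% of those at 2, 86% at 3 and 94% at 4 (50 genes each), with 7 false calls among 12867 unchanged genes. The changed genes were first raised to a minimum expression level, so these rates need not hold for lower genes. The procedure found 5 of 5 changed lists and called 0 of 20 unchanged lists. Every gene of a changed list rose, by a log2 fold change of 1 to 4. The simulation therefore does not test lists with smaller or mixed changes. The simulated genes were drawn independently of each other, so this does not test camera on lists whose members vary together. Alternatives were pseudocounts of 0.1 and 0.01, no filter, a filter of 5 FPKM in 3 libraries, median-ratio, TPM and quantile scaling, a fit without the trend, array weights, robust variances, the replicate number as a block and leaving out each library.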

Results

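Whole-ovary RNA was sequenced from 6 goats (Capra hircus) in the follicular phase of the oestrous cycle, the days before ovulation when follicles grow and the corpus luteum of the previous cycle regresses. The samples were 3 Jintang black goats, a breed the labels call prolific, and 3 Tibetan goats, a breed the labels call non-prolific. The question was which ovarian transcripts differ between the breeds. Expression was given as FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) for 17504 genes. The sum of FPKM per library ran from 602255 to 682801, and between 12617 and 13131 genes reached 1 FPKM. Absolute depth is unknown. The spacing of low FPKM values put the relative depth of the libraries between 0.927 and 1.026 (Tibetan 1 set to 1), so that no library was more than 1.107 times as deep as another. Values below are mean ± SD with n = 3 goats per breed, and fold changes are Jintang minus Tibetan on the log2(FPKM + 1) scale, which understates the change of low genes.

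The first principal component held 45.6% of the variance and the second 23.5%, and neither separated the breeds. Jintang 1 and Jintang 2 lay at 38.2 and 66.8 on the first component, Tibetan 3 at 9.55, Jintang 3 at -24.8, Tibetan 2 at -32.5 and Tibetan 1 at -57.2. Across genes, the closest pair of libraries by Spearman correlation was Tibetan 2 and Jintang 3 (0.964). Jintang 3 correlated less with Jintang 1 (0.892) and Jintang 2 (0.859). Genes are not independent replicates, and these correlations describe the libraries only.

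**Figure D1:**
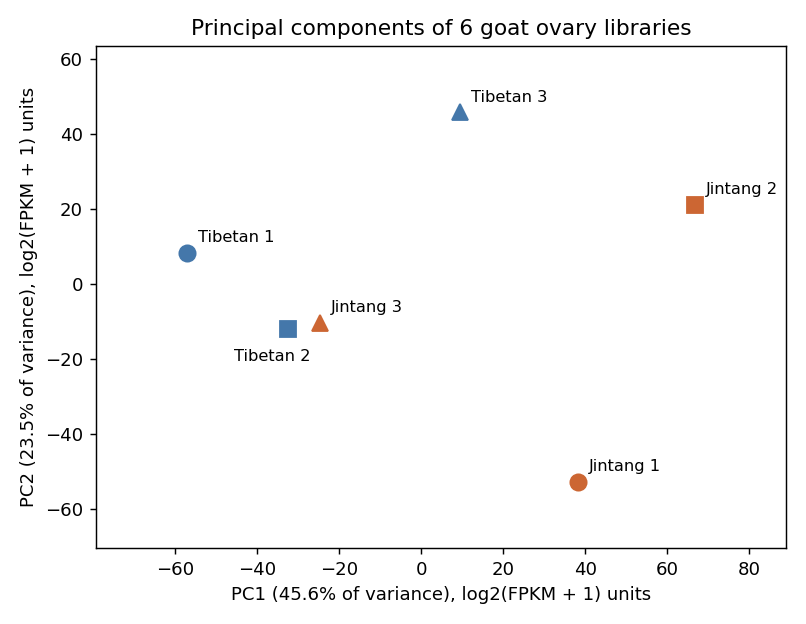
Principal components of log2(FPKM + 1) over 13067 genes, with 1 point per goat ovary (blue, Tibetan; orange, Jintang). Jintang 3 lies at -24.8 on the first component, beside Tibetan 2 at -32.5, while Jintang 1 and Jintang 2 lie at 38.2 and 66.8.

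Among the genes with the smallest p in the Jintang direction were CRYBA4, a crystallin (GeneID 102183171), at 0.0733 ± 0.127 FPKM in Tibetan and 7.60 ± 3.46 in Jintang ovaries, and TREM2, a myeloid cell receptor, at 2.05 ± 2.86 and 28.5 ± 16.8 FPKM. SLC6A6, the taurine transporter, averaged 1.72 ± 0.247 and 20.1 ± 13.2 FPKM, and SRPX2 averaged 2.30 ± 0.626 and 11.2 ± 4.15 FPKM. The transcription factor RUNX2 stood at 6.43 ± 0.327 and 17.6 ± 3.78 FPKM, the interleukin receptor IL1R1 at 13.8 ± 6.27 and 46.0 ± 14 FPKM, and the growth factor BMP6 at 10.1 ± 0.90 and 26.2 ± 6.90 FPKM. NPTX2, a secreted pentraxin, ranged from 0.07 to 3.54 FPKM in Tibetan and from 9.73 to 107 FPKM in Jintang ovaries. The potassium channel gene KCNMA1 averaged 1.02 ± 0.584 and 4.70 ± 1.18 FPKM. KIT, the receptor for KIT ligand, averaged 5.02 ± 1.86 and 23.3 ± 11.2 FPKM. In each of these 10 genes all 3 Jintang ovaries lay above all 3 Tibetan ovaries. None passed the test: the limma adjusted p was 0.343 for CRYBA4 (log2 fold change 2.92, SE 0.39) and 0.743 for the others, whose log2 fold changes ran from 1.26 to 3.98.

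In the opposite direction, HSPA6, a stress-inducible member of the HSP70 family (GeneID 102185412), stood at 15.03 ± 1.79 FPKM in Tibetan and 2.69 ± 0.880 FPKM in Jintang ovaries (log2 fold change -2.14, SE 0.29, limma adjusted p = 0.343). Another inducible HSP70 gene, HSP70.1, averaged 631 ± 361 and 145 ± 35.3 FPKM, and its co-chaperone DNAJB1 averaged 92.1 ± 18.7 and 38.8 ± 7.20 FPKM. The labels do not record how the animals or the tissue were handled before extraction. Some HSP70 genes are near-identical to each other, so their reads can be shared between copies and the level of each such gene is uncertain. KRT7, a keratin of simple epithelia, averaged 7.39 ± 3.12 and 1.45 ± 0.577 FPKM, and the clock gene PER1 averaged 45.0 ± 14.4 and 16.8 ± 3.65 FPKM. OLFM2 averaged 36.0 ± 0.772 and 12.3 ± 5.96 FPKM, SAP25 20.8 ± 4.64 and 7.34 ± 2.06 FPKM, and CDC42EP2 18.2 ± 2.82 and 8.04 ± 0.735 FPKM. The last 2 genes named by the rule were TRIM10, at 5.64 ± 1.97 and 1.22 ± 0.605 FPKM, and C2H2orf72, at 4.73 ± 1.44 and 0.727 ± 0.514 FPKM. All 3 Jintang ovaries lay below all 3 Tibetan ovaries in each of these 10 genes. The limma adjusted p was 0.743 for all but HSPA6.

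Of the 13067 genes tested with limma, 0 were higher and 0 were lower in Jintang ovaries at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 806 genes, 368 higher and 438 lower in Jintang ovaries, where 653 were expected by chance. With median-ratio scaling, which moved the median log2 fold change of all genes from -0.10 to 0.02, this split became 456 higher and 308 lower. The ranges of the breeds did not overlap in 1293 genes (9.90%), and chance gives 10% with 3 libraries against 3. The smallest adjusted p was 0.197, for LOC102169412, which is annotated as a transcribed pseudogene and is named after its values were seen. It is listed at 0 in all 3 Jintang libraries and at 5.52, 7.57 and 11.7 FPKM in the Tibetan libraries. Without Jintang 3, limma called 13 genes higher and 0 lower, and 1874 genes had an unadjusted p under 0.05.

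The genes named in advance for their roles in ovarian function gave no call either. BMPR1B (GeneID 100861211), the bone morphogenetic protein receptor in which a variant raises litter size in sheep, averaged 10.4 ± 5.32 FPKM in Tibetan and 30.4 ± 10.7 FPKM in Jintang ovaries (log2 fold change 1.51, SE 0.40, limma adjusted p = 0.743), with all 3 Jintang ovaries above all 3 Tibetan ovaries. The progesterone receptor PGR stood at 11.1 ± 1.27 and 5.31 ± 3.41 FPKM, and PTGS2, the inducible prostaglandin synthase, at 2.00 ± 0.382 and 0.773 ± 0.413 FPKM, both without overlap and both at an adjusted p of 0.743. The aromatase gene CYP19A1 averaged 8.22 ± 6.95 and 2.70 ± 3.65 FPKM, the oestrogen receptor ESR1 17.2 ± 2.02 and 12.1 ± 6.11 FPKM, and follistatin (FST) 24.3 ± 20.4 and 43.2 ± 7.34 FPKM. The gonadotrophin receptors overlapped between the breeds, with FSHR at 2.29 ± 2.98 and 6.04 ± 4.58 FPKM and LHCGR at 22.0 ± 27.6 and 16.1 ± 11.7 FPKM.

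Several of these genes varied more between goats of one breed than between breeds. STAR, which carries cholesterol into mitochondria for steroid synthesis, stood at 8.91, 28.6 and 139 FPKM in Tibetan 1, 2 and 3, and at 139, 3130.4 and 30.8 FPKM in Jintang 1, 2 and 3. A gene listed as 3BHSD, taken here for HSD3B1, followed at 28.1, 57.3 and 482 FPKM against 105, 4269.8 and 53.3 FPKM. CYP17A1 (LOC102182663), the androgen-producing enzyme of theca cells, was at 16.3, 152 and 719 FPKM against 1.99, 4.24 and 103 FPKM. The inhibin subunit INHA was at 51.4, 198 and 1194 FPKM against 9.56, 132 and 144 FPKM, and INHBA at 38.3, 66.5 and 15.6 FPKM against 122, 29.9 and 21.9 FPKM. Anti-Müllerian hormone (AMH), a product of small growing follicles, exceeded 2 FPKM only in Tibetan 2 (20.7) and Jintang 3 (44.3). The oocyte growth factors were low: GDF9 averaged 2.12 ± 1.53 and 1.24 ± 0.924 FPKM, and BMP15, which did not reach the filter, had its highest value in Jintang 3 (1.73 FPKM). The log2 fold changes of LHCGR, 3BHSD, INHBA and AMH changed sign when single libraries were left out, reaching -0.80 for LHCGR (without Tibetan 1), -0.30 for 3BHSD (without Jintang 2), -0.41 for INHBA (without Jintang 1) and -0.63 for AMH (without Jintang 3).

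**Figure D2:**
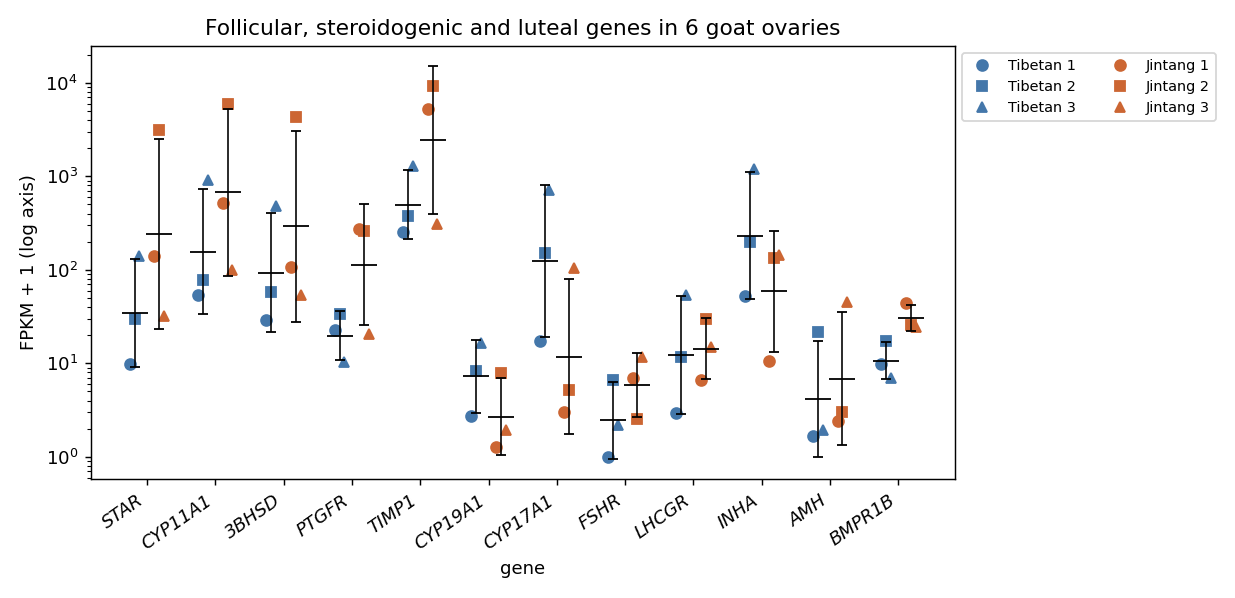
FPKM + 1 (log axis) of 12 follicular, steroidogenic and luteal genes, with 1 point per goat ovary (blue, Tibetan; orange, Jintang) and black bars for the mean ± SD of log2(FPKM + 1), n = 3 per breed. STAR spans 30.8 to 3130.4 FPKM within the Jintang ovaries, and BMPR1B has all 3 Jintang ovaries above all 3 Tibetan ovaries.

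Of 27 gene lists fixed before the data were examined, 25 had at least 3 tested members, and 9 passed camera with its preset correlation of 0.01, all 9 towards Jintang. No list passed when camera estimated the correlation between genes, nor with fry's directional test (smallest adjusted p 0.883), and no member of any list passed the limma test over all genes. Each list past the threshold is therefore given with both adjusted p-values.

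Luteal cell markers were higher in Jintang ovaries by camera with the preset correlation (10 of 10 tested members positive, median log2 fold change 1.79, adjusted p = 0.000957), with an adjusted p of 0.669 with an estimated correlation. PTGFR, the receptor through which prostaglandin triggers luteal regression, was at 274 and 259 FPKM in Jintang 1 and 2 and between 9.23 and 32.3 FPKM in the other 4 ovaries. The protease inhibitor TIMP1 was at 5303.8 and 9215 FPKM in Jintang 1 and 2 and between 253 and 1298 FPKM elsewhere. The prolactin receptor PRLR reached 53.4 FPKM in Jintang 1 and at most 2.03 FPKM elsewhere. None of the 10 members passed adjusted over the list alone. The call was lost without Jintang 2 (median 0.46, adjusted p = 0.108), and the median was 2.85 without Jintang 3.

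Steroidogenesis genes (13 of 17 positive, median 0.81, adjusted p = 0.0300, and adjusted p = 0.669 with an estimated correlation) and genes of cholesterol synthesis and uptake (20 of 22 positive, median 0.49, adjusted p = 0.00345, and adjusted p = 0.681 with an estimated correlation) passed camera with the preset correlation. NR5A2, a nuclear receptor that activates steroidogenic genes, stood at 4.73 ± 2.95 FPKM in Tibetan and 50.8 ± 61.4 FPKM in Jintang ovaries without overlap, SRD5A1 at 6.14 ± 1.85 and 16.3 ± 11 FPKM, and CYB5A at 55.9 ± 15.7 and 36.1 ± 15.4 FPKM. SCAP, a sterol-sensing escort protein, averaged 32.0 ± 8.83 and 74.7 ± 37.6 FPKM, INSIG1 15.7 ± 13.4 and 29.9 ± 18.4 FPKM, PMVK 12.1 ± 9.34 and 28.8 ± 24.4 FPKM, and STARD4 7.54 ± 3.52 and 16.6 ± 14 FPKM. None of these genes passed the limma test. The steroidogenesis list shares LHCGR, STAR, 3BHSD, CYP11A1, SCARB1 and FDX1 with the luteal list, so the calls of these lists are not independent. Jintang 2 had the highest value of 21 of the 22 cholesterol genes. Without it the medians became -0.52 for cholesterol genes and -0.06 for steroidogenesis genes, and neither list passed (adjusted p = 0.267 and 0.757). Both calls were also lost without Tibetan 1 (medians 0.07 and 0.21) or without Tibetan 2 (0.16 and 0.81). Both were kept without Tibetan 3 (medians 1.27 and 1.22), Jintang 1 (0.94 and 1.19) or Jintang 3 (1.04 and 1.45). The steroidogenesis call was lost with median-ratio scaling (median 0.94, adjusted p = 0.105), quantile normalization (0.80, adjusted p = 0.0528) or no filter on low values (0.81, adjusted p = 0.0601), where its median was close to or above 0.81.

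Nuclear-encoded oxidative phosphorylation genes passed with a small shift (17 of 19 positive, median 0.29, adjusted p = 0.00252, and adjusted p = 0.669 with an estimated correlation). SDHA, a subunit of succinate dehydrogenase, averaged 78.8 ± 22.8 and 140.0 ± 68.6 FPKM, and the complex I subunits NDUFB5 27.6 ± 7.98 and 39.1 ± 7.95 FPKM, NDUFV1 41.3 ± 9.12 and 69.8 ± 43.6 FPKM, and NDUFS1 22.7 ± 11 and 39.9 ± 26.8 FPKM. Jintang 2 had the highest value of 15 of the 19 genes. The mean log2 values of the list in Jintang 1 (6.33) and Jintang 3 (6.47) lay below those in Tibetan 2 (6.52) and Tibetan 3 (6.58). They lay above that in Tibetan 1 (6.05). The call was lost without Jintang 2 (median 0.05, adjusted p = 0.580) or without Tibetan 1 (median 0.14, adjusted p = 0.120), and the median was at most 0.52 (without Jintang 1).

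Cell cycle genes were higher in Jintang ovaries by camera with the preset correlation (31 of 33 positive, median 0.95, adjusted p = 7.74e-08), with an adjusted p of 0.669 with an estimated correlation. CDK1, the kinase that drives mitosis, stood at 4.48 ± 3.53 and 11.5 ± 3.91 FPKM without overlap. AURKB averaged 1.06 ± 0.660 and 5.37 ± 5.24 FPKM, TYMS 9.02 ± 3.32 and 20.4 ± 14.3 FPKM, and CENPF 1.92 ± 1.47 and 8.02 ± 8.59 FPKM. Jintang 2 had the highest value of 31 of the 33 genes and Tibetan 1 the lowest of 21. Without Jintang 2 the median was 0.24 and the call was lost (adjusted p = 0.0582), without Tibetan 1 the median was 0.54, and it was at most 1.44 (without Jintang 1).

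Genes of the LH surge and ovulation formed the only list whose mean expression was higher in every Jintang ovary than in every Tibetan ovary (13 of 18 positive, median 0.66, camera adjusted p = 0.00252, and adjusted p = 0.669 with an estimated correlation). Fry's test for change in either direction gave an adjusted p of 0.0453. Among its members 8 had an unadjusted p under 0.05, and 1, RUNX2, passed adjusted over the list alone. With 3 ovaries against 3, 1.25 of 25 lists are expected to have every Jintang mean above every Tibetan mean by chance, so this order alone is no evidence. PLAU, the urokinase gene, averaged 4.55 ± 2.59 and 28.5 ± 21.6 FPKM, and PTX3, a matrix protein of the expanding cumulus, 2.06 ± 1.21 and 12.8 ± 11.6 FPKM, both without overlap. SNAP25 went the other way (38.0 ± 20.8 and 12.8 ± 6.43 FPKM), as did PGR and PTGS2, which are induced by the surge in granulosa cells. The camera call held with each library left out, with medians from 0.49 (without Tibetan 1) to 0.81 (without Tibetan 2).

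Markers of macrophages and myeloid cells were higher in Jintang ovaries by camera with the preset correlation (16 of 17 positive, median 1.17, adjusted p = 1.19e-07), with an adjusted p of 0.669 with an estimated correlation. The scavenger receptor MSR1 averaged 4.62 ± 3.96 and 24.4 ± 21.4 FPKM without overlap, the mannose receptor MRC1 5.08 ± 2.13 and 16.8 ± 12.3 FPKM, the integrin ITGAM 1.99 ± 0.917 and 7.55 ± 6.28 FPKM, and the lysozyme gene listed as S-LZ 3.90 ± 5.69 and 17.2 ± 14.4 FPKM. Jintang 1 had the highest value of 15 of the 17 markers and Tibetan 1 the lowest of 15. The mean log2 value of the list in Jintang 2 (3.63) lay below those in Tibetan 2 (4.07) and Tibetan 3 (3.82). The call held with each library left out, and the median was 0.51 without Jintang 1 and 1.82 without Jintang 2.

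Endothelial markers (15 of 17 positive, median 0.49, adjusted p = 2.87e-05, and adjusted p = 0.669 with an estimated correlation) and fibroblast and extracellular matrix genes (15 of 21 positive, median 0.58, adjusted p = 8.55e-05, and adjusted p = 0.669 with an estimated correlation) also passed camera with the preset correlation and with each library left out. FLT4, a receptor of lymphatic endothelium, averaged 4.79 ± 2.85 and 11.7 ± 2.98 FPKM without overlap, and the vascular markers CDH5 21.0 ± 5.66 and 44.0 ± 18.3 FPKM, PECAM1 23.9 ± 14.5 and 66.7 ± 37.1 FPKM, and PLVAP 2.47 ± 2.16 and 22.4 ± 22.6 FPKM. The fibrillin gene FBN1 averaged 15.3 ± 4.43 and 30.2 ± 7.90 FPKM without overlap, and the matrix genes POSTN 9.81 ± 5.40 and 76.4 ± 65.7 FPKM, LUM 73.6 ± 70.0 and 364 ± 394 FPKM, and MFAP5 1.98 ± 0.885 and 7.51 ± 7.13 FPKM. With a library left out the endothelial median ran from 0.39 (without Tibetan 1) to 0.69 (without Jintang 3). The fibroblast median ran from 0.38 (without Tibetan 3) to 0.75 (without Tibetan 2). In both lists the mean log2 value of Jintang 3 lay below that of Tibetan 2 and above those of Tibetan 1 and 3. Jintang 3 and Tibetan 2 stood at 4.09 and 4.45 for endothelial markers, and at 6.92 and 6.98 for fibroblast genes.

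**Figure D3:**
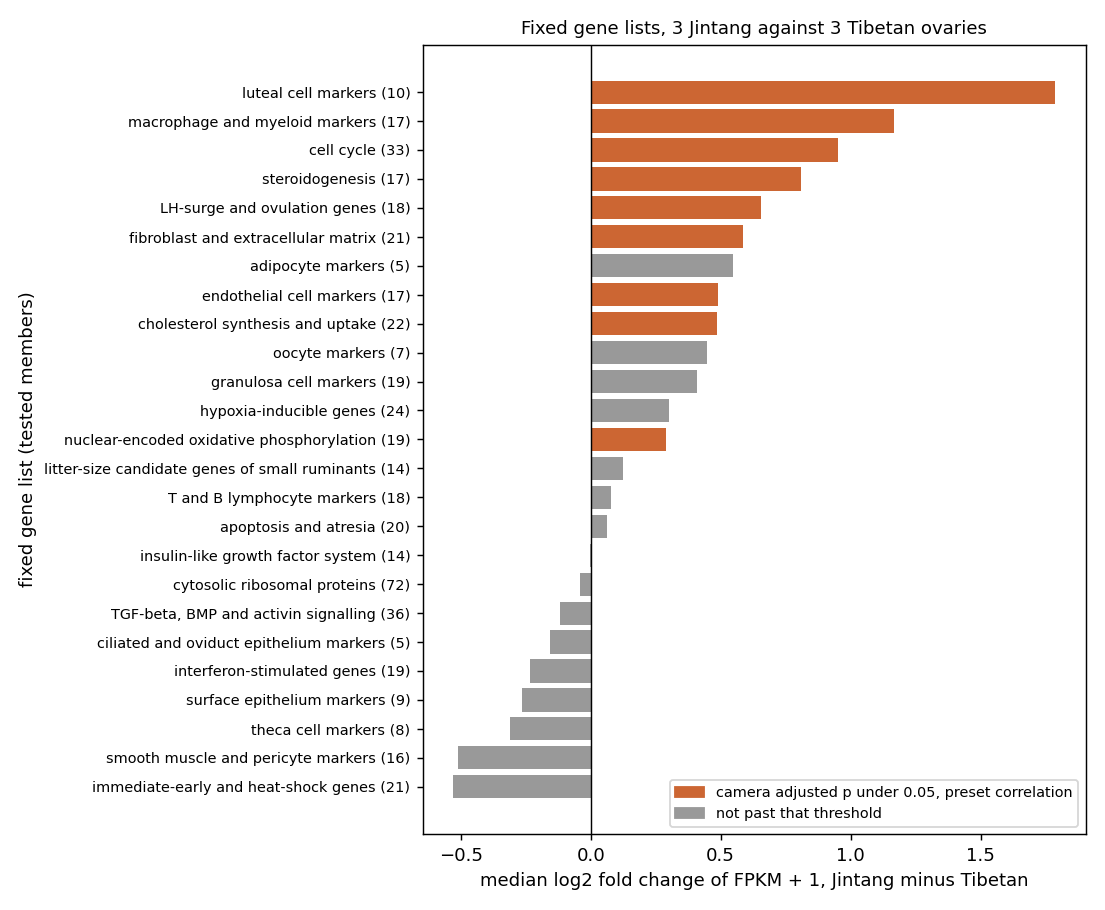
Median log2 fold change of FPKM + 1 (Jintang minus Tibetan, n = 3 per breed) of the 25 tested gene lists, with the number of tested members in brackets. Orange bars are the 9 lists past camera with a preset correlation of 0.01, from 0.29 to 1.79; none of them passed with an estimated correlation.

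Lists of follicle cell types and of fecundity genes did not pass at the main settings, and leaving out 1 library turned the sign of most of their medians. Granulosa cell markers had 12 of 19 members positive (median 0.41, camera adjusted p = 0.297), with WT1 at 36.8 ± 15.9 and 16.9 ± 13.0 FPKM, GATM at 63.5 ± 32.5 and 25.7 ± 16.3 FPKM, and KITLG at 4.67 ± 2.36 and 14.9 ± 13.8 FPKM. Their median ran from -0.35 (without Jintang 3) to 0.58 (without Jintang 2). Theca cell markers had 5 of 8 negative (median -0.31, adjusted p = 0.552), with NR2F2 at 78.4 ± 8.60 and 52.6 ± 22.7 FPKM. Their median ran from -0.79 (without Jintang 3) to 0.04 (without Tibetan 2), and was 0.03 without Jintang 2. Oocyte markers had 5 of 7 positive (median 0.45, adjusted p = 0.15). Their median ran from -0.09 (without Jintang 3) to 1.14 (without Tibetan 2), and was -0.07 without Tibetan 1. KIT was the 1 oocyte marker past the limma test adjusted over the list alone, and KIT is also made by other ovarian cells. ZP3, a protein of the egg coat, averaged 2.74 ± 3.92 and 5.41 ± 4.42 FPKM. Of the litter-size candidate genes 8 of 14 were positive (median 0.12, adjusted p = 0.153), and 2, BMPR1B and KIT, passed adjusted over the list alone. This list passed camera with a filter of 5 FPKM in 3 libraries (median 0.33, adjusted p = 0.0475), and its median ran from -0.20 (without Tibetan 1) to 0.16 (without Jintang 1) over the libraries left out, with -0.04 without Jintang 3. TGF-beta, BMP and activin signalling had 15 of 36 positive, with BMP2 at 8.57 ± 3.18 and 3.01 ± 1.65 FPKM without overlap and SMAD7 at 6.09 ± 3.65 and 22.1 ± 18.1 FPKM. The median of that list was -0.12 while its mean (0.01) and camera's direction were positive (adjusted p = 0.389). The median was -0.0005 with median-ratio scaling and ran from -0.22 (without Jintang 3) to -0.002 (without Jintang 2). The insulin-like growth factor system split 7 and 7 (adjusted p = 0.562), with STC2 at 0.820 ± 0.356 and 5.35 ± 4.12 FPKM, IGF1 at 20.8 ± 8.78 and 12.8 ± 4.20 FPKM, and IGF2 at 813 ± 759 and 282 ± 149 FPKM. Its median lay just under 0, at 0.12 with median-ratio scaling and from -0.24 (without Jintang 1) to 0.36 (without Jintang 2) over the libraries left out, and its mean and camera's direction were positive.

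Immediate-early and heat-shock genes had 16 of 21 members negative (median -0.53, camera adjusted p = 0.148), 7 of the 21 at an unadjusted p under 0.05 (IER3 and SOCS3 among them positive) and 1, DNAJB1, past the test adjusted over the list alone. EGR1 averaged 190.4 ± 112 and 60.6 ± 32.8 FPKM, JUN 93.9 ± 14 and 51.0 ± 19.0 FPKM, and IER3, in the opposite direction, 26.8 ± 8.52 and 89.8 ± 57.6 FPKM. Without Jintang 1 this list passed (adjusted p = 5.9e-05), and its median ran from -0.54 (without Jintang 1) to -0.18 (without Jintang 2). Hypoxia-inducible genes had 17 of 24 positive (median 0.30, adjusted p = 0.0586), with ANGPTL4 at 30.8 ± 2.20 and 18.8 ± 7.64 FPKM. They passed with a filter of 5 FPKM in 3 libraries (0.0184), with array weights (0.0104), and without Tibetan 3 (0.00502) or Jintang 3 (0.00334). Their median was at least 0.09 (without Jintang 1). Smooth muscle and pericyte markers had 12 of 16 negative (median -0.51, adjusted p = 0.155), with CNN1 at 294 ± 145 and 135 ± 94.1 FPKM and SYNPO2 at 46.9 ± 16.0 and 24.9 ± 16.4 FPKM. They passed without Jintang 3 (median -1.0, adjusted p = 0.00690), and their median was nearest to 0 at -0.21 (without Jintang 2).

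Among the other lists, surface epithelium markers had 5 of 9 negative (median -0.26, adjusted p = 0.429), with KRT7 past the test adjusted over the list alone and EPCAM at 3.59 ± 0.546 and 2.1 ± 0.814 FPKM; their median ran from -0.50 (without Jintang 2) to 0.44 (without Tibetan 3). Interferon-stimulated genes had 13 of 19 negative (median -0.23, adjusted p = 0.347), with IFIT2 at 6.31 ± 1.59 and 4.30 ± 0.751 FPKM, and passed without Tibetan 1 (0.0488) or Jintang 1 (0.0394); their median ran from -0.34 (without Jintang 1) to -0.04 (without Tibetan 3). Apoptosis and atresia genes had 12 of 20 positive (median 0.06, adjusted p = 0.389; from -0.11 (without Tibetan 1) to 0.18 (without Tibetan 3) over the libraries left out). T and B lymphocyte markers had 10 of 18 positive (median 0.08, adjusted p = 0.389), with CD8A at 3.84 ± 2.89 and 8.97 ± 3.32 FPKM. Lymphocyte and oocyte markers passed without Tibetan 2 (0.0108 and 0.00243) or Jintang 2 (0.00703 and 0.0272), but without Tibetan 1 (medians -0.18 and -0.07) or Jintang 3 (-0.36 and -0.09) both medians were negative. Adipocyte markers had 3 of 5 positive (median 0.55, adjusted p = 0.552), with CIDEA at 3.29 ± 0.425 and 6.41 ± 1.70 FPKM and DGAT2 at 9.05 ± 2.24 and 4.01 ± 2.65 FPKM, and ciliated epithelium markers 2 of 5 (median -0.16, adjusted p = 0.868). The adipocyte median ran from -0.03 (without Jintang 2) to 0.91 (without Jintang 3) and the ciliated one from -0.42 (without Jintang 3) to 0.13 (without Jintang 2). Cytosolic ribosomal protein genes had 45 of 72 negative, and their median (-0.04) and mean (-0.07) were negative while camera's direction was positive (adjusted p = 0.552). Their median was 0.09 with median-ratio scaling, and the list passed upwards without Tibetan 2 (median 0.23) and downwards without Tibetan 3 (median -0.35). Erythrocyte markers had too few members over the filter to be tested. The haemoglobin gene HBBC was at 33.0 FPKM in Jintang 2 and at most 0.30 FPKM elsewhere. No mitochondrially encoded gene matched an entry of the files.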

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

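The alternatives were planned. The count of genes higher in Jintang ovaries was 0 in limma under every alternative but 1, and 0 to 13 over the libraries left out, with 13 without Jintang 3. The count lower was 0 throughout. Unadjusted counts ran from 336 (without Tibetan 1) to 1874 (without Jintang 3), and array weights gave 1227. Of the 9 lists past the threshold, 0 passed with an estimated correlation and 0 with the directional test of fry. Both camera runs used the same values and differed in whether the correlation between genes was preset or estimated. The loss of the 9 calls therefore came with that choice. How much of the loss was due to the size of the correlation itself was not tested. For cell cycle genes the unadjusted camera p went from 3.1e-09 with the preset correlation to 0.239 with the estimated one. Why the lists did not pass with fry was not tested. Of the 9 lists, 8 or 9 were kept under other settings, 4 without Jintang 2, 6 without Tibetan 1, 7 without Tibetan 2 and 9 without each other library. Over all lists, 8 to 11 passed under other settings and 6 to 11 over the libraries left out. Signs of named genes changed only on leaving out a library: APOD ran from -0.14 to 1.62, PTCH1 -0.80 to 0.041, RSPH1 -0.42 to 0.13, LIPE -0.031 to 0.91, RPS13 -0.91 to 0.040, LHCGR -0.80 to 1.30, 3BHSD -0.30 to 2.85, INHBA -0.41 to 0.80 and AMH -0.63 to 1.93. None of these passed the test, and the causes were not tested. With the replicate number as a block, 0 genes were higher, 0 lower, and 8 lists passed, without steroidogenesis (adjusted p = 0.0517); 581 genes had an unadjusted p under 0.05. Goats with the same number did not deviate together (correlations across genes of -0.02, -0.21 and -0.47). These values gave no sign that the numbers pair the animals, but a smaller effect shared by number cannot be excluded. Depth is unknown, so counting error was not separated from the spread between goats. In simulation, with changed genes raised to a minimum expression level, 48% of those with a log2 fold change of 2 were recovered.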

Other observations

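The tests in this part, and the genes named in it outside the rule, were chosen after the values were seen; the luteal list was fixed before. Single ovaries stood out by cell type and tissue state within each breed. Jintang 1 was rich in myeloid transcripts: the complement genes C1QA, C1QB and C1QC were at 303, 375 and 326 FPKM, against at most 79.2 FPKM in any other ovary, and the lysosomal marker CD68 was at 233 FPKM against at most 67.3 FPKM. Collagen gene COL1A1 was at 2931 FPKM in Jintang 1, 1737 FPKM in Jintang 2 and between 441 and 825 FPKM in the other 4 ovaries. Jintang 2 was rich in mitotic transcripts, with MKI67 at 26.4 FPKM (at most 4.37 elsewhere), CCNB1 at 47.3 FPKM (at most 8.24) and CDC20 at 44.1 FPKM (at most 7.88), together with the cholesterol receptor SCARB1 at 1099 FPKM (at most 156).

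The egg coat genes ZP3 and ZP4, the oocyte gene NPM2 and HSD17B1 were highest in Tibetan 2 and Jintang 3. ZP3 was at 7.24 and 10.5 FPKM, ZP4 at 4.31 and 4.88 FPKM and NPM2 at 3.67 and 4.06 FPKM in these ovaries, and at most 3.57, 1.00 and 0.78 FPKM elsewhere. The oestradiol-forming enzyme HSD17B1 was at 22.4 and 23.8 FPKM there and at most 4.13 FPKM elsewhere. Not all oocyte markers followed, and Jintang 3 had the highest value of 3 of the 7 tested. FBXW12 was highest in Tibetan 1 (36.1 FPKM) and KIT in Jintang 1 (31.1 FPKM). Tibetan 3 had the highest CYP17A1, INHA, LHCGR and CYP19A1 of the 6 ovaries. A gene without a symbol, GeneID_102173080, reached 17800.6 FPKM in Tibetan 3 and at most 1029 FPKM elsewhere. Genes listed at 0 in all 3 libraries of one breed and at 0.5 FPKM or more in all 3 of the other numbered 7. They were LOC102169412, IGIP and GNG13 in Tibetan ovaries, and CCL1, CYSLTR2, OIP5 and LOC102171392 in Jintang ovaries. The other splits of the 6 libraries into 3 and 3 gave between 2 and 10 such genes. Besides PER1, 7 clock genes (PER2, NR1D1, DBP, TEF, CIART, BHLHE41 and ARNTL) were compared, and the breeds overlapped in all 7.

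The splits of the 6 libraries into 3 and 3 number 10, the real one included, so the share with a result as large is never under 0.1. For genes at an adjusted p under 0.05, 10 of the 10 splits gave as many as the real 0, and the highest other split gave 10. For genes at an unadjusted p under 0.05 it was 2 of 10 (806 in the real split, 2888 in the highest other), and for gene lists 7 of 10 (9 in the real split, 15 in the highest other). The split of Tibetan 1, Tibetan 2 and Jintang 3 against the rest gave the 10 genes and the 2888, and 28.7% of its genes did not overlap. This split was picked as the highest and any split matches a count of 0, so its called genes alone do not show a structure of the samples. Every other split had at most 11.6% of genes without overlap. The highest split is also the split by breed with Jintang 3 and Tibetan 3 exchanged.

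The first pattern is a set of genes higher in Jintang 1 and 2 than in the other 4 libraries. Without Jintang 3, 13 genes passed: MSMB was at 586 and 394 FPKM against at most 8.05 elsewhere, CRABP1 at 88.2 and 82.3 FPKM against at most 2.04, and APOA1 at 6824 and 3581 FPKM against at most 308, and in 4 of the 13 (CRYBA4, SLC6A6, ADAMTS14 and LOC102179867) Jintang 3 also lay above every Tibetan library. Scaling does not account for them, since over all 6 libraries their median log2 fold change of 2.92 stayed at 2.87 or more under the 3 other scalings. Depth differed by a factor of at most 1.107, below the smallest fold of 1.97 (CRYBA4) between Jintang 1 or 2 and the highest other library. Luteal tissue left in these ovaries is a possible explanation. Only 2 of the 10 tested luteal markers, PTGFR and TIMP1, were higher in both than in each other library. Against Jintang 3 alone, 9 were higher in both. Others, such as 3BHSD, CYP11A1 and SCARB1, are also on the steroidogenesis list and were higher in Tibetan 3 than in Jintang 1. CYP11A1 was at 5995 FPKM in Jintang 2, 515 in Jintang 1 and 912 in Tibetan 3. The count of 2 therefore cannot decide, and luteal tissue stays open.

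The second pattern is that Jintang 3 lies nearest to the Tibetan libraries. Depth does not account for it, since Jintang 3 and Tibetan 2, its closest match, differ most in relative depth (1.107). A swap of labels would need a Tibetan library that fits better with Jintang 1 and 2. Tibetan 3 does so for Jintang 2 (Pearson correlation 0.904 against 0.895 and 0.899 with the Tibetan libraries, a gap of -0.0089 to the lower one) but not for Jintang 1 (0.878), which leaves a swap open. A single wrong label cannot be told apart from a difference in ovarian structures. Genes on in one breed and off in the other numbered 7, against 10 in the split that exchanges Jintang 3 and Tibetan 3. Such counts ran from 2 to 10 over the splits, and an exchange does not model a single wrong label, so they cannot decide. The Pearson correlation of Jintang 3 was 0.968 with Tibetan 2, and 0.902 and 0.875 with Jintang 1 and 2. Right labels would give the opposite order only if breed outweighed other differences between ovaries, which was not tested.

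The third pattern is untested as a group. Its 12 heat-shock genes were listed after the values of several of them were seen. Of these, 10 had a lower mean log2 value in Jintang ovaries (not HSPE1 and HSPD1). All Jintang ovaries lay below all Tibetan ovaries in 5 (HSPA6, HSP70.1, DNAJB1, BAG3 and HSPB8). None of the 12 passed limma (smallest adjusted p 0.343), nor did the fixed list of immediate-early and heat-shock genes (0.148). Luteal tissue in Jintang 1 and 2 would leave Jintang 3 out, but Jintang 3 lay below every Tibetan library in 10 of the 12. HSPA6, HSP70.1 and DNAJB1, among the 10, were named for a small p in this direction, so they are no independent test. Scaling does not account for the median of -0.74, which came no nearer to 0 than -0.61 under the 3 other scalings. The median of -0.74 may reflect handling or temperature of the animals or tissue before extraction, which the labels do not record and which cannot be told apart from breed here.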
